A study of Zea mays with 24 samples.

How the data were processed

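Leaf RNA of 4 maize inbred lines, B73, Mo17, W23 and Wf9, was measured on a pilot Affymetrix maize GeneChip, on which a set of short oligonucleotide probes, a probe set, reports each transcript sequence. Per the labels, each sample pooled leaves 3 to 5 of several greenhouse plants. Growth, harvest and RNA extraction were carried out 3 times for each line, and each RNA was hybridised to 2 arrays, which gave 24 arrays. The authors deposited 1 value table of 8475 probe sets, whose values are intensities on a linear scale (probe set signal). Per the submitters' processing notes, the values were made with MAS5 in GCOS, the Affymetrix software that summarises the probes of a probe set into 1 signal per array. The software version, the scaling target and any present or absent calls are not given in the sources used here. The 2% trimmed mean of the deposited signal lay between 250.15 and 250.24 on all 24 arrays once exact zeros were left out, so each array had been scaled by the authors before deposit.

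The table held 213 exact zeros, all on B73 replicate 3 array 1. Of these, 22 were control probe sets, among them 12 of the 18 spiked bacterial control probe sets, whose signal was at least 67.1 on the other 23 arrays. The zeros were treated as missing values, so that the second array of that RNA alone gave the value of those probe sets. The log2 values of that array had a correlation of 0.948 with its technical partner across probe sets, against 0.994 or more in the other 11 technical pairs. Probe sets are not independent, and these correlations only rank the arrays. The array was kept, and each count was also made without it.

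Each array was rescaled to the same 2% trimmed mean, the 129 control probe sets were left out, and log2(signal + 16) was taken, so that differences of dim probe sets are understated. The log2 values of the 2 technical arrays of an RNA were averaged, and the 12 biological replicates, 3 per line, were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with line as the only term. The labels name 3 biological replications per line, which the p-values treat as separate samples. A moderated F-test compared the 4 lines, and 6 contrasts compared pairs of lines, with Benjamini-Hochberg adjustment over 8346 probe sets and a threshold of 0.05. A probe set counted as higher or lower in 1 line where each of its 3 contrasts with the other lines passed the threshold with the same sign and a log2 difference of at least 1. No filter on dim probe sets was used. The number of arrays limits the precision, and no count or depth exists for these data.

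A background level was set at a signal of 16.7, the 99th percentile of 44 control probe sets for bacterial transcripts and tags that were not spiked. Of the tested probe sets, 1900 (22.8%) were at or below this level on all 24 arrays. Where all arrays of a line were at or below it, a fold was computed against the higher of this level and the probe set's own signal and is given as a lower bound ("at least"), as it is where all 3 replicates of the line were below it. Where only some replicates were below it, as in bx1, aox1, gst18, gst24, gst31 and pr5, the fold is understated. Folds are ratios of geometric means over replicates with the background level as a floor, and are given against the other line nearest in level unless a pair is named. Means and SDs are of the linear signal over the 3 biological replicates of a line.

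Genes were named through the platform annotation given with the series, and names were brought up to date through the gene table of the maize assembly Zm-B73-REFERENCE-NAM-5.0, from which no coordinates are given because no build is named for the array. A single gene symbol was given for 862 probe sets, several symbols for 0, and no gene in the table used here for 7613. Of the 862 named probe sets, controls included, 838 matched a gene in the reference table. The 852 of them that were tested stood for 579 genes, matched or not. The suffixes that mark probes shared with other sequences were carried by 1447 tested probe sets, whose signal can hold more than 1 transcript of a gene family. Among genes named below, these include the probe sets of gst31, grp1, cpi2, gln3, sut1, sh2, gpc3, Zlp, gz27, NIP3-1 and LOC542057. They also include gst19 as higher in B73, and GST39 as lower in B73 and higher in Mo17.

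The rule for named genes was fixed before the data were examined. It took, per line, up to 8 named probe sets higher and up to 8 lower than in each other line, ranked by the smallest of the 3 differences. Per pair of lines it took the 3 highest and 3 lowest differences of log2(signal + 16) past the threshold with no overlap between replicates. Per gene list it took up to 3 members with the smallest F-test p, and the 2 brightest members of the lists for seed, pollen and root. It took 1 probe set per gene, and probe sets of the same gene that go the other way are mentioned. Some genes that met the rule are not reported here. Also fixed were 21 gene lists, of which 19 had a measured probe set; the lists for the anthocyanin pathway and for transposons had none. Lists of at least 5 probe sets were tested with limma's camera, each line against the mean of the others, with the preset correlation of 0.01 and with an estimated correlation. The lists had been fixed with gene symbols and with phrases to be found in gene descriptions, but the annotation holds no descriptions, so membership rests on symbols alone. A list can therefore miss members of its family, such as gst18, gst19, gst24, gst31 and GST39, Sod4A, aoc1, rpp2a-4 and prpl35-1, and its counts are not those of the family. A further 5 lists were written after the annotation had been seen.

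The labels give each line replicate numbers 1 to 3. Deviations from the line means were compared between same-numbered replicates over the 3295 probe sets with a mean log2 signal above 7. They correlated with r between 0.24 and 0.62 in B73, Mo17 and Wf9, and differently numbered ones between -0.62 and 0.22, so the numbers pair the samples of those 3 lines. This pairing comes from the data, since the labels do not say that lines of the same number were grown together. W23 replicate 2 did not pair with replicate 2 of the other lines.

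The fit was tested on simulated data before use. In simulated replicates for B73 against W23 with 8346 probe sets, of which 200 were changed in W23, the contrast called 8.96% of 67 probe sets changed 1.5-fold, 26.9% of 67 changed 2-fold and 71.2% of 66 changed 4-fold, all in the right direction. Unchanged probe sets made up 4.62% of the F-test calls. The simulated noise was independent between probe sets and between replicates, unlike the real deviations, so these rates may not hold for the real data. The alternatives tried were pseudocounts of 1 and 64, deposited values without rescaling, quantile normalization, removal of the dimmest probe sets, a replicate block, each technical array alone, all 24 arrays with a random block, no mean-variance trend, array weights, fits of only the 2 lines compared, and leaving out each replicate in turn. The call for a named gene counted as lost where its adjusted p was no longer under 0.05. The minimum log2 difference of 1 was not applied again, so calls for a line can fail more often than stated.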

Results

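Signal was measured for 8346 maize probe sets in leaves of 4 inbred lines, each with 3 biological replicates of 2 technical arrays. B73 and Mo17 are the parents of a widely used maize mapping population, and B73 is the line of the maize reference genome. W23 and Wf9 are older inbred lines. The design asks how far leaf transcript levels, as read by 1 array type, differ between lines beyond the differences between replicates of a line. The median signal per array ranged from 46.7 to 62.8. Over bright probe sets, the SD of the log2 differences between 2 arrays of the same RNA was 0.0914 to 0.213 in 11 technical pairs and 0.858 in B73 replicate 3. Between biological replicates of a line it ran from 0.390 to 0.811, except that W23 replicates 2 and 3 differed with an SD of only 0.197. B73 replicate 3 array 1 was left out of these distances between replicates.

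**Figure D1:**
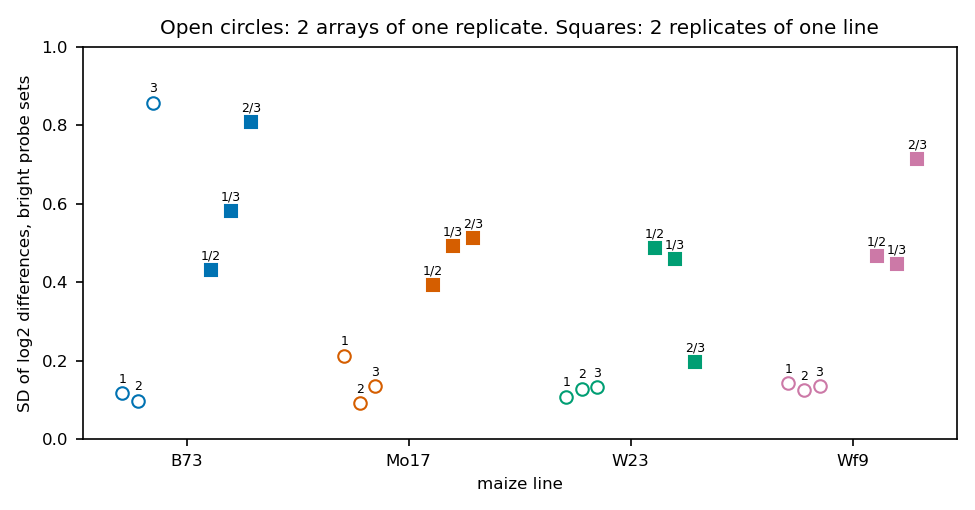
SD of log2 signal differences over bright probe sets (no unit), by maize line. Open circles are the 2 technical arrays of each replicate, and squares are means over array pairs from 2 replicates of a line, with replicate numbers beside the points and B73 replicate 3 array 1 left out of the squares. B73 replicate 3 stands out among the technical pairs with 0.858, and W23 replicates 2 and 3 are the closest pair of replicates with 0.197.

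Probe sets for photosynthesis genes were among the brightest. None of the 7 probe sets for mesophyll enzymes of the C4 cycle differed among the 4 lines, and neither did any of the 7 for bundle sheath and Calvin cycle enzymes. The rbcs1 probe set for the small subunit of Rubisco had a mean signal of 6625 ± 1989 in B73, 7083 ± 406 in Mo17, 8187 ± 561 in W23 and 6502 ± 1233 in Wf9 (SD, n = 3), and the adjusted p of the F-test was 0.560. The list of light harvesting and photosystem proteins had 1 of 8 probe sets past the threshold (1 adjusted over the list alone), fdx3, a ferredoxin, with 614.1 ± 147 in Mo17 and 1614 ± 149 in W23. None of the 12 probe sets for heat shock proteins and chaperones passed. A test that misses the threshold does not show equal levels.

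In the list of starch and sucrose metabolism, 9 of 14 probe sets differed among the lines (10 adjusted over the list alone). That was 64.3%, against 26.6% of the other named probe sets (Fisher's exact test, adjusted p = 0.0456 over 24 lists), but counted by gene the adjusted p was 0.273. None of the other lists fixed in advance passed this test, with adjusted p of 0.160 or more. They included sut1, a sucrose transporter, with 581.1 ± 28.3 in B73 and between 1083 and 1178 in the other lines, and sbe1, a starch branching enzyme, with 30.3 ± 5.15 in Wf9 and 109 ± 29.6 in Mo17. Another was sh2, a large subunit of ADP-glucose pyrophosphorylase, which was above background only in W23, at 21.6 ± 1.91. In the list of antioxidant enzymes, which does not hold Sod4A, 3 of 6 differed (3 over the list alone), namely apx2, an ascorbate peroxidase, CAT3, a catalase, and sod2, a superoxide dismutase, whose call was lost in 4 of the alternatives. CAT3 had 276 ± 42.9 in B73 and 62.3 ± 5.39 in W23. For nitrogen assimilation it was 4 of 10 (4 over the list alone), from the glutamine synthetase genes gln3 and gln5, the latter lost in 6 of the alternatives. The gln3 probe set was at or below background in B73, at 9.20 ± 0.984, and had 80.6 ± 11.1 in Mo17.

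The list of glutathione transferases, which conjugate toxins and herbicides, had 7 of 21 probe sets past the threshold (9 over the list alone). It held no measured cytochrome P450 and not gst18, gst19, gst24, gst31 or GST39, which also differed. GST26 had 56.8 ± 8.93 in Mo17 and 61.0 ± 18.3 in W23 but 14.3 ± 6.82 in B73 and 13 ± 5.11 in Wf9, and gst10 ranged from 78.1 ± 13.4 in Wf9 to 279 ± 83.2 in Mo17. The list of hormone synthesis and response, without aoc1, had 4 of 9 (4 over the list alone). ACO31, an oxidase of ethylene synthesis, had 77.0 ± 26.6 in B73 and 244 ± 64.1 in Wf9, and dhn2, a dehydrin, had 315 ± 103 in B73 and 124 ± 26.8 in W23, a call lost in 12 of the alternatives. All 3 histone probe sets differed (3 over the list alone), from his1 and his2b5. The lignin list had 1 gene, BM1, an alcohol dehydrogenase of lignin synthesis, with both probe sets past the threshold (2 over the list alone) and 739 ± 52.1 in B73 against 1198 ± 126 in W23.

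For the cytoskeleton and common reference genes it was 6 of 39 (2 over the list alone), with the alpha-tubulin tua3 at 367 ± 38.9 in Wf9 and 917 ± 78.5 in Mo17, and the glyceraldehyde-3-phosphate dehydrogenases gpc3 and GPC1. GPC1 had 6773 ± 617 in Mo17 and 4222 ± 888 in B73, and the calls for GPC1 and gpc3 were lost in 13 and 3 of the alternatives. Of the 14 probe sets in the list of ribosomal proteins, which lacks rpp2a-4 and prpl35-1, 2 differed (2 over the list alone), rpl30 and rpl39, and of the 11 for pathogenesis-related and wound-induced proteins 2 did (2 over the list alone), pr5 and Zlp. Regulators of shoot meristem and leaf development had 2 of 14 (2 over the list alone). These were ZMM2, a MADS-box gene, with 25.2 ± 4.68 in Mo17 and a level at or below background in B73, and gl8, an enzyme of cuticular wax synthesis, with 408 ± 47.2 in W23 and 153 ± 12.6 in Mo17. In the benzoxazinoid list bx1 alone, of 3 probe sets, passed the threshold (1 over the list alone).

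Markers of other organs were mostly dim. None of the 9 probe sets in the seed list differed, and 8 of them were at or below background on all 24 arrays, among them gz27, a gamma zein. The brightest, vpp1, encodes a proton pump of the vacuole rather than a storage protein and had 2551 ± 1517 in B73. In the pollen list 3 of 9 differed (4 over the list alone), and 5 were at background. The profilins PRO4 and PRO5, which bind actin, were the brightest, with 2851 ± 52.3 and 2316 ± 394 in B73. PRO4 was lower in Mo17, at 1843 ± 238, and the call for PRO5 (adjusted p = 0.0484) was lost in 14 of the alternatives. The pls1 probe set, whose gene encodes an acyltransferase of lipid synthesis, had 72.3 ± 18.8 in Mo17. Both probe sets of the root list differed (2 over the list alone). The zrp4 probe set had 42.0 ± 29.7 in B73 and 10.9 ± 1.57 in W23, and tip2, an aquaporin, had 89.0 ± 81.8 in W23 and 15.0 ± 11 in Wf9. These calls were lost in 7 and 10 of the alternatives.

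Over all tested probe sets, 2549 of 8346 (30.5%) differed among the 4 lines in limma's F-test, and 232 of the 852 named ones (27.2%) did. Of the 3295 bright probe sets it was 1182 (35.9%). Another 124 of the probe sets called were at or below background on all 24 arrays. None of the 15 lists large enough to test passed as shifted as a whole in any line. Of 60 tests of a list in a line, 0 passed the threshold with camera, the smallest adjusted p was 0.158 with the preset and 0.735 with an estimated correlation, and 5 and 4 had an unadjusted p under 0.05. Leaving out Wf9 replicate 3 brought 1 list past it, the cytoskeleton and reference genes, lower in Wf9 with an adjusted p of 0.0346 at the preset correlation and 0.941 at an estimated one.

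**Figure D2:**
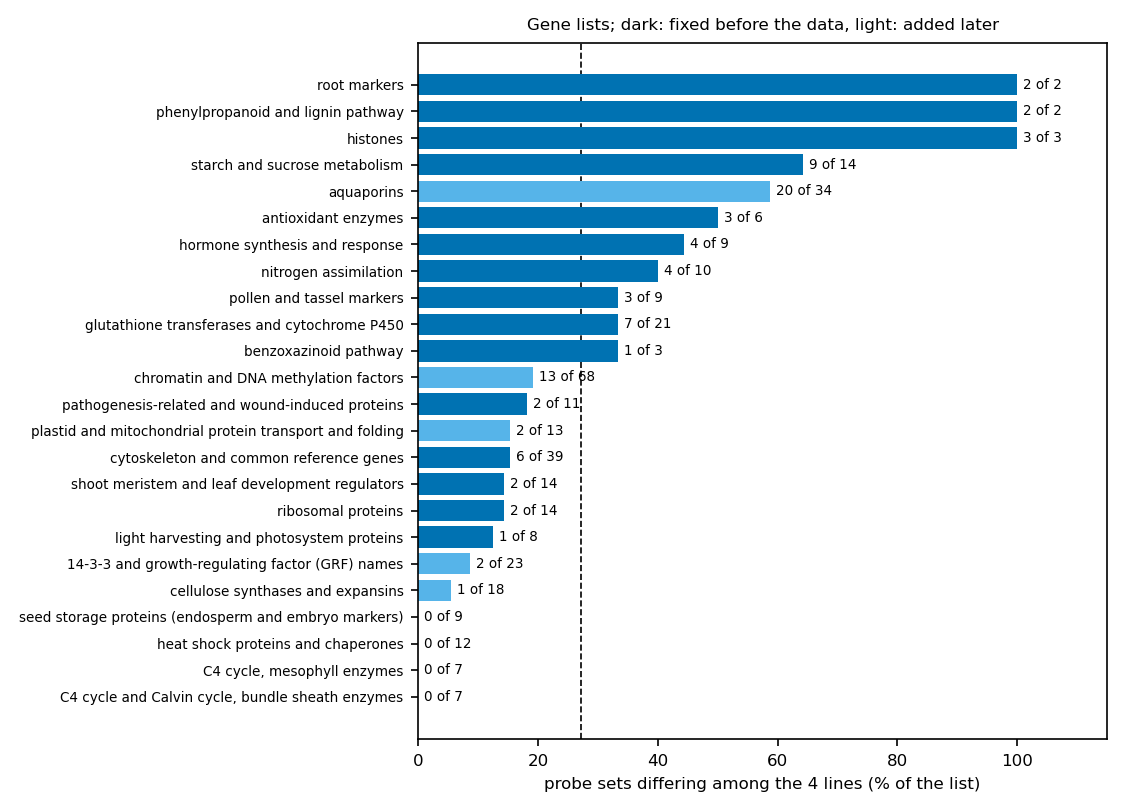
Share of the probe sets of each gene list that differed among the 4 lines (percent of the list), with the counts beside the bars. Dark bars are lists fixed before the data were examined, light bars lists added later, and the dashed line marks 27.2%, the share over all named probe sets. Lists for C4 enzymes, heat shock and seed storage stand at 0, and starch and sucrose metabolism at 9 of 14.

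B73 leaves had higher signal for a spermidine synthase, a ribosomal protein and a superoxide dismutase than leaves of each other line. So did a dimmer probe set for an enzyme of jasmonate synthesis. The spermidine synthase gene spds2 had 983 ± 400 in B73 and was 4.97-fold above Wf9, the nearest line, with a log2 difference of 3.08 ± 0.27 (SE) from the mean of the others. The ribosomal protein gene rpl30 was 4.99-fold above the nearest line, and Sod4A, a copper/zinc superoxide dismutase, had 1247 ± 503 and was 2.48-fold above it. For aoc1, an allene oxide cyclase of jasmonate synthesis, the figure was 2.50-fold, from a probe set with 121 ± 10.5 in B73. A brighter aoc1 probe set was not higher in B73, with 243 ± 47.5 there, 251 ± 64.4 in Mo17 and 256 ± 8.08 in W23. Of the glutathione transferases, gst19 had 147 ± 102 in B73 and was 4.88-fold above Mo17, on a probe set with a suffix of shared probes. A brighter gst19 probe set was not higher in B73, with means of 210 there, 244 in Mo17 and 207 in W23. The gst31 probe set, which carries such a suffix too, had 896 ± 957 in B73, with an SD above its mean and a call lost in 4 of the alternatives. The other named genes were LOC541887, annotated as a transcribed pseudogene, at 5.11-fold, and LOC542441 at 2.07-fold.

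Lower in B73 than in each other line were grp1, a glycine-rich protein, with 534 ± 248 against 2897 to 3093 elsewhere (log2 difference -2.56 ± 0.19), hox3, a homeobox gene, at 79.8 ± 22.4, and GST39, a glutathione transferase, at 25.4 ± 8.35. Of 5 other grp1 probe sets, 2 went the other way and 1 of these differed among the lines. In all, 92 probe sets were higher and 42 lower in B73 than in each other line, and 8 and 5 of these were named. A pseudocount of 64 gave 50 and 12, and a pseudocount of 1 gave 123 and 85.

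Mo17 was set apart by bx1, the enzyme that makes free indole in the first step of the benzoxazinoid defence pathway. Its signal was 3620 ± 139 in Mo17, 251 ± 256 in B73, 104 ± 36.0 in W23 and 29.5 ± 16.3 in Wf9, a log2 difference of 5.20 ± 0.45 from the mean of the others (adjusted p at most 0.000216 against each line). Also higher in Mo17 were ivr2, a soluble invertase that splits sucrose, with 2295 ± 789 and 2.79-fold above W23, nrx1, a nucleoredoxin, 3.27-fold above the nearest line, and dbf1, a transcription factor of the drought response, 2.62-fold, a call lost in 6 of the alternatives. GST39 had 482 ± 46.3 in Mo17, 2.17-fold above Wf9.

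The largest named decrease in Mo17 was in aba1, whose other name in the gene table is asr1, for a small protein induced by abscisic acid and stress. It had 78.0 ± 12.7 in Mo17 and 1008 ± 43.4 in W23, the next lowest line, and its second probe set went the same way. Mo17 was also lower for gst24, at 18.3 ± 5.36 and 11.5-fold below the nearest line, eif7, a translation initiation factor, 8.33-fold, and rpl39, a ribosomal protein, 4.89-fold. The water channels PIP1-3 and TIP1-1 were 2.87-fold and 2.43-fold lower, vdac1a, a channel of the outer mitochondrial membrane, 2.51-fold, and trh2, a thioredoxin, 2.12-fold. Another PIP1-3 probe set did not bear out that size, with 814 ± 62.5 in Mo17 and 941 ± 193 in W23. Its log2 difference from the mean of the others was -0.64, against -2.57. In all, 49 probe sets were higher and 91 lower in Mo17 than in each other line, 7 and 11 of them named. A pseudocount of 64 gave 32 and 60, and a pseudocount of 1 gave 69 and 128.

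W23 leaves lacked measurable signal for mbd111, a methyl-CpG-binding domain protein, and for his1, a linker histone, both well above background in the other lines. Neither gene had another named probe set. Sequence differences under the probes, which could not be tested, may also lower the signal. The mbd111 probe set was at or below background on all W23 arrays, at 1.95 ± 0.958, against 249 to 294 elsewhere, at least 14.7-fold lower (adjusted p = 7.40e-08). The his1 probe set had 10.3 ± 1.38 in W23 and 531 ± 268 in B73, at least 13-fold lower than in Wf9. Also lower were rpp2a-4, an acidic ribosomal protein, 6.64-fold, vip3 4.10-fold, and apx2, the ascorbate peroxidase, with 299 ± 21.7 and 3.28-fold. Higher in W23 were gst18, with 196 ± 58.4 and 9.13-fold above the nearest line, NIP3-1, an aquaporin, 2.60-fold, and LOC542057 at least 2.08-fold. In all, 48 probe sets were higher and 99 lower in W23 than in each other line, and 6 of each were named. A pseudocount of 64 gave 21 and 61, and a pseudocount of 1 gave 72 and 132. W23 replicates 2 and 3 were unusually alike, and with their mean counted as 1 replicate the counts stayed within 1.5 times.

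Wf9 had lower signal than each other line for a plastid ribosomal protein, a water channel and a histone acetyltransferase. The plastid ribosomal protein gene prpl35-1 had 453 ± 78.1 in Wf9 and 1844 to 2178 elsewhere, a log2 difference of -2.12 ± 0.13. TIP2-1, a water channel of the vacuolar membrane, had 1119 ± 483 and was 2.48-fold lower than in W23, and hac106, the histone acetyltransferase, 3.71-fold. A second TIP2-1 probe set went the same way but less far. Its log2 difference from the mean of the others was -0.51, against -1.68. Further genes were gst19, at 19.3 ± 0.357 and 9.74-fold lower, aoc1 7.30-fold, pdlk2, a pyruvate dehydrogenase kinase, 3.31-fold, csr1 2.90-fold, and annexin2, a calcium-dependent membrane binding protein, at or below background and at least 3.38-fold lower. The gst19 and aoc1 probe sets here differ from those higher in B73, and in B73 they had 210 ± 113 and 243 ± 47.5, close to Mo17.

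Higher in Wf9 were PIP1-3, with 2334 ± 458 and 2.38-fold above the nearest line, zmCL2-2 2.90-fold, and LOC542697 2.24-fold, whose call was lost in 9 of the alternatives. A further probe set of PIP1-3, which shares its cluster number with a probe set of the related pip1-2, was lowest in Wf9, at 1044 ± 149. In all, 33 probe sets were higher and 102 lower in Wf9 than in each other line, 4 and 15 of them named. A pseudocount of 64 gave 13 and 55, and a pseudocount of 1 gave 56 and 143. Of the genes named for a line or a list, the calls for CAT3, ivr2, nrx1, pls1, Zlp and zmCL2-2 were each lost in 2 of the alternatives, and those for BM1, GST39 as lower in B73, hac106 and his2b5 in 1.

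**Figure D3:**
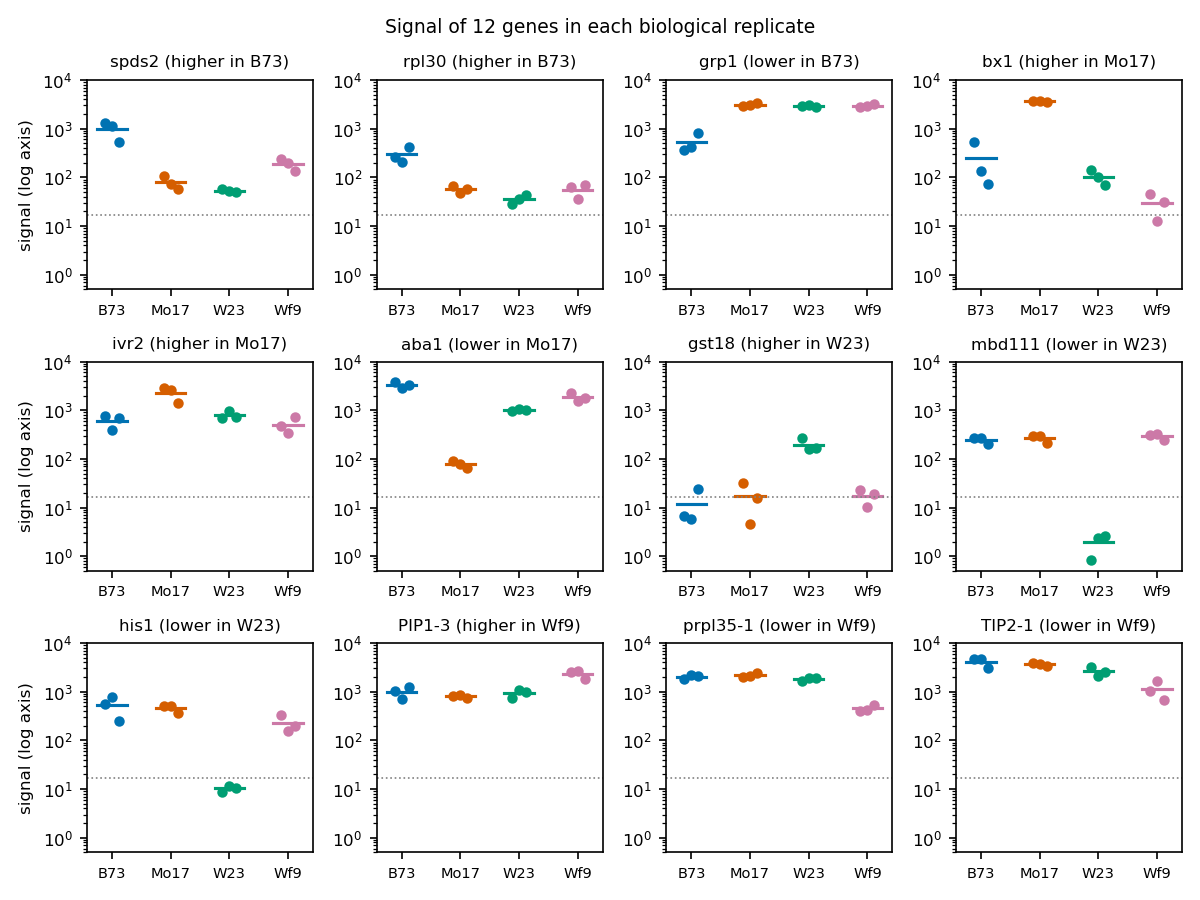
Signal on a log axis (arbitrary units) of 12 named genes in each of the 3 biological replicates (points) of 4 maize lines, with the mean as a horizontal line and the background level of 16.7 dotted. Replicates of bx1 in Mo17 lie close together around 3620, and mbd111 and his1 lie below background in W23.

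Between B73 and Mo17, the named genes with the largest differences on the log2(signal + 16) scale, in each direction, included aba1, bx1 and the water channel pip2-5. The aba1 signal was 42.9-fold higher in B73 (log2 difference 5.16 ± 0.18, adjusted p = 1.98e-08), pip2-5 was 15.9-fold higher, with 1567 ± 169 in B73 and 104 ± 37.5 in Mo17, and gst31 19.5-fold. Lower in B73 were bx1, 20.6-fold, GST39, 18.2-fold, and cpi2, an inhibitor of cysteine proteases, 12.1-fold, of which another probe set went the other way. In all 1223 probe sets passed the threshold, 639 higher and 584 lower in B73. Of the 569 at least 2-fold apart on the log2(signal + 16) scale, 360 were higher and 209 lower in B73. A fit of these 2 lines alone gave 743.

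Among named genes higher in B73 than in W23 was pr5, a thaumatin-like defence protein, with 948 ± 930 in B73 and, below background in each W23 replicate, 9.70 ± 4.72 in W23, at least 40.4-fold. Also higher in B73 were gst31, at least 32.7-fold, and his1, at least 28.6-fold. Lower in B73 were gst18, 12.6-fold, cpi2, 6.52-fold, and grp1, 5.79-fold. For cpi2, 2 other probe sets went the other way, and for grp1, 3 did. The contrast called 1335 probe sets, 703 higher and 632 lower in B73, and 396 and 234 of these were at least 2-fold apart.

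Higher in B73 than in Wf9 were pip2-5, 15.6-fold with 101 ± 20.8 in Wf9, pr5, 13.5-fold, and gst31, 9.0-fold, whose call was lost in 5 of the alternatives. Lower in B73 were GST39, 8.56-fold, grp1, 5.88-fold, and LOC542697, 3.00-fold. Of other probe sets, 3 of 5 for grp1 and 1 of 4 for gst31 went the other way, and 1 of those for grp1 differed among the lines. The contrast called 1207 probe sets, 634 higher and 573 lower in B73, with 369 and 190 at least 2-fold apart. Array weights gave a share higher in B73 of 42.3%, against 52.5%. A fit of the 2 lines alone gave 632, and the fit of all lines without Wf9 replicate 1 gave 791.

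Higher in Mo17 than in W23 were bx1, 36.3-fold with a log2 difference of 4.97 ± 0.55, his1, at least 27.5-fold, and mbd111, at least 15.7-fold. Higher in W23 were pip2-5, by 17.0-fold, aox1, the alternative oxidase of mitochondria, by 19.2-fold (404 ± 12.2 against 20.6 ± 11.5), and aba1, by 13-fold. The contrast called 1159 probe sets, 593 higher and 566 lower in Mo17, with 318 and 300 at least 2-fold apart.

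Mo17 signal was 127-fold above that of Wf9 for bx1 (log2 difference 6.39 ± 0.55, adjusted p = 7.75e-06). Also higher in Mo17 were cpi2, 13.2-fold, and pip2c, a water channel, 10.7-fold. Lower in Mo17 were aba1, 23.6-fold, PIP1-3, 13.3-fold, of which another probe set went the other way, and eif7, 14.2-fold. A further PIP1-3 probe set differed less, with 814 ± 62.5 in Mo17 and 2334 ± 458 in Wf9. The contrast called 1361 probe sets, 683 higher and 678 lower in Mo17, with 368 and 323 at least 2-fold apart.

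Higher in W23 than in Wf9 were pip2-5, 16.7-fold, aox1, 16.3-fold, and gst18, 9.82-fold. Lower in W23 were mbd111, at least 17.5-fold (log2 difference -4.11 ± 0.19), his1, at least 13-fold, and rpp2a-4, 7.26-fold. The contrast called 1273 probe sets, 621 higher and 652 lower in W23, with 370 and 338 at least 2-fold apart. Array weights, whose estimation did not converge, gave over 1.5 times as many calls in all 6 pairs.

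**Figure D4:**
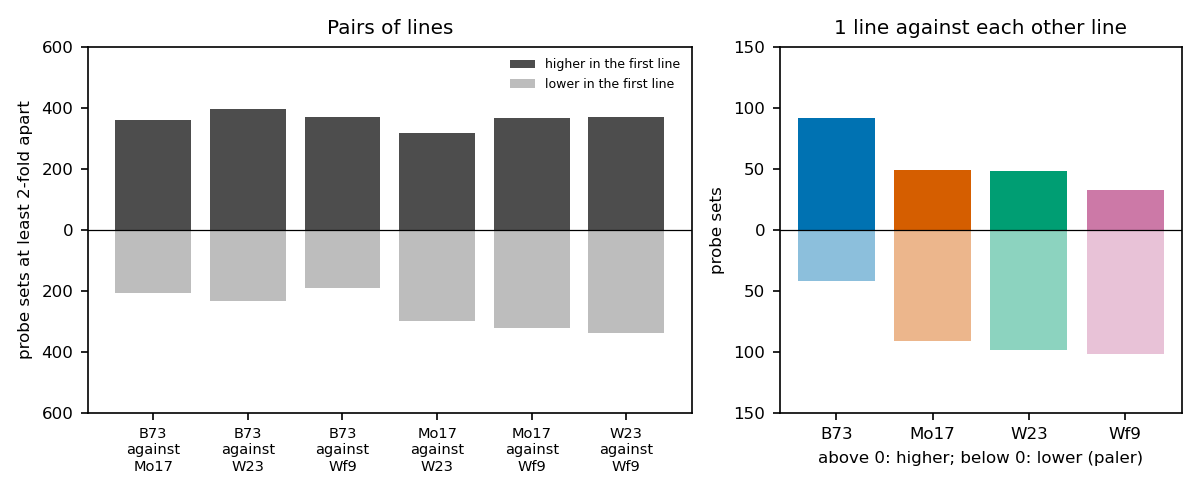
Left, number of probe sets past the threshold and at least 2-fold apart for 6 pairs of lines, higher in the first line above 0 and lower below. Right, number of probe sets higher (above 0) or lower (below 0, paler) in 1 line than in each other line; B73 has 92 higher and 42 lower, and Wf9 33 and 102.

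As a sign of RNA quality, the log2 ratio of 3' to 5' signal of control probe sets for cyclophilin was between 0.53 and 0.84 in line means, and for ubiquitin between 0.45 and 0.74, with exact permutation p over 15400 splits of 0.329 and 0.401. For GAPDH it was 1.04 ± 0.21 in B73 and 0.63 ± 0.22 in Mo17 (exact permutation p = 0.0136, adjusted over 4 ratios 0.0543). The control for actin had a 3' signal below background.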

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

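B73 replicate 3 array 1 lay far from the other arrays of its line in 1 of 3 array measures. It held 213 exact zeros, and the other 5 B73 arrays held 0, a gap equal to the whole range of the group. The same rule was applied to the median signal (47.6 against 53.7 to 60.5) and the median correlation with the other arrays of the line (0.925 against 0.954 to 0.985), in which this array was the lowest without passing the same limit (Dixon's test). The 6 arrays of a line are 3 pairs from the same RNA and not 6 independent samples. About 1 in 20 groups passes such a limit by chance, but with 5 arrays at 0 any number of zeros would pass it, so that rate says nothing about the zeros. Against its technical partner, 598 of 3295 bright probe sets were over 2-fold apart, and in the other 11 technical pairs the highest number was 0. No explanation of the zeros was tested.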

How the results depend on the processing

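The line-specific counts moved with the pseudocount, which sets how far apart dim probe sets can lie, and with the minimum difference. Leaving out the dimmest probe sets kept every count within 1.5 times. A pseudocount of 1 gave 85 probe sets lower in B73 and 56 higher in Wf9. A pseudocount of 64 gave 50 higher and 12 lower in B73, 32 and 60 in Mo17, 21 and 61 in W23, and 13 and 55 in Wf9. Without the minimum log2 difference, adjusted p alone gave 175 higher and 102 lower in B73, 124 and 157 in Mo17, 120 and 172 in W23, and 127 and 162 in Wf9. Array weights gave 5424 probe sets differing among the lines, and 2304 (B73 against Mo17), 3335 (B73 against W23), 3626 (B73 against Wf9), 2148 (Mo17 against W23), 2406 (Mo17 against Wf9) and 3601 (W23 against Wf9) for the pairs. The estimation of these weights did not converge. They ran from 0.182 for B73 replicate 3 to 5.77 for Wf9 replicate 1, so few replicates carried those counts. With them the share of calls higher in the first line went from 52.5% to 42.3% for B73 against Wf9, from 52.2% to 48.7% for B73 against Mo17 and from 50.2% to 48.0% for Mo17 against Wf9, so the balance turned in these pairs. The balance also turned in some pairs under other alternatives. With quantile normalization it went from 51.2% to 48.0% for Mo17 against W23 and from 48.8% to 50.4% for W23 against Wf9. Fits of only the 2 lines compared gave 743 for B73 against Mo17 and 632 for B73 against Wf9.

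Leaving out 1 replicate at a time gave 2045 to 2806 probe sets differing among the lines. The ranges were 855 to 1227 for B73 against Mo17, 909 to 1370 for B73 against W23, 791 to 1324 for B73 against Wf9, 836 to 1464 for Mo17 against W23, 978 to 1644 for Mo17 against Wf9 and 905 to 1627 for W23 against Wf9. For probe sets higher and lower in 1 line they were 83 to 104 and 35 to 45 in B73, 40 to 55 and 78 to 97 in Mo17, 37 to 51 and 81 to 99 in W23, and 30 to 40 and 73 to 118 in Wf9. List shifts ranged from 0 to 1.

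With a replicate block, which pairs the samples by replicate number, 2960 probe sets differed among the lines, and the pairs of lines gave 1490, 1661, 1503, 1402, 1563 and 1558, in the order used above. The block places W23 replicate 2 with replicate 2 of the other lines, from which its deviations run the other way (r between -0.64 and -0.37), so it is not a sound pairing for W23. The cause of these moves was not tested. Camera was not run for the fit of all 24 arrays with a random block.

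Alternatives added after the data had been seen left out B73 replicate 3 array 1, averaged W23 replicates 2 and 3 as 1, did both, joined the first to the replicate block, or kept the zeros. Without that array 2763 probe sets differed among the lines, and with the W23 replicates averaged 2056 did. Averaging them gave 903 for B73 against W23, 837 for Mo17 against W23 and 908 for W23 against Wf9. Pairs without W23 fell too, to 1083 for B73 against Mo17, 1040 for B73 against Wf9 and 1217 for Mo17 against Wf9.

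Of 119 results for named genes, 117 passed 0.05 as reported, and 25 lost it under at least 1 alternative, judged by adjusted p alone. A gene taken by more than 1 rule counts for each, as PRO5, tip2 and zrp4 do. The number that changed direction was 0. Results taken from a list could not change it, since their value was the spread between the highest and lowest line. Among the 3366 values 140 were weaker, 99 of them with a replicate left out. PRO5, GPC1, dhn2, tip2, LOC542697, zrp4, dbf1 and gln5 were lost most often.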

Other observations

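Tests chosen only after the result was seen were those without B73 replicate 3 array 1 and of the growth of W23 replicate 2, and the aquaporin list was written after the annotation had been seen.

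Probe sets of aquaporins, the channels that pass water and small solutes through membranes, differed among the lines more often than other named probe sets, but counted by gene the difference did not pass its test. Of 34 aquaporin probe sets 20 passed limma's F-test (58.8%), and 28 did when adjusted over the list alone. PIP2-6, of the plasma membrane, had 343 ± 76.4 in B73 and 81.0 ± 27.4 in Mo17 (SD, n = 3). TIP2-2, of the vacuolar membrane, had 67.2 ± 15.5 in Mo17 and 21.0 ± 2.11 in Wf9, and NIP2-3 had 255 ± 81.5 in B73 and 864 ± 144 in W23. Among the other named probe sets 25.9% differed (Fisher's exact test, adjusted p = 0.00221 over 24 lists). Counted by gene, it was 15 of 28 aquaporin genes against 169 of 551 others (exact p = 0.0201, adjusted 0.241). Signal level was excluded as the cause of the excess by probe set, since 0 of 10000 random lists with matched signal held as many, and the highest held 19. These lists drew single probe sets, and signal was not matched in the count by gene. Probe sets marked as shared between related genes could not make up this excess, since 33 of the 34 carry no such suffix. Of those 33, 57.6% differed, against 28.4% of the other named probe sets without it (one-sided Fisher's exact p = 0.000619). That comparison used nearly the same probe sets again and is no separate evidence. Binding of related transcripts that no suffix marks was not tested. Biological variation between lines may remain, and so may sequence differences under the probes, which could not be tested without probe sequences.

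Of 68 probe sets for chromatin and DNA methylation factors 13 differed (13 adjusted over the list alone), among them hac108, a histone acetyltransferase, with 191 ± 34.2 in B73 and 108 ± 24.4 in Mo17, and mbd106, with 276 ± 38.1 in Wf9 and 570 ± 52.3 in Mo17. Cellulose synthases and expansins had 1 of 18 (1 over the list alone), CesA-3, with 91.9 ± 6.28 in Wf9 and 38.4 ± 5.31 in Mo17. Names of 14-3-3 proteins and growth-regulating factors had 2 of 23 (0 over the list alone), and plastid and mitochondrial transport and folding had 2 of 13 (2 over the list alone). The latter were tha4, of the thylakoid translocation machinery, with 260 ± 86.4 in B73 and 67.8 ± 4.17 in Wf9, and bsd2, a chaperone of Rubisco assembly.

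B73 was the only line with more probe sets higher than lower, 92 and 42, where Mo17, W23 and Wf9 had 130 higher and 292 lower between them (odds ratio 4.90, 95% confidence interval 3.17 to 7.68). Probes designed on sequences closer to B73 might bind its transcripts better, and a second probe set might then not bear out the difference. The second one was the brightest with the same cluster number under the other name prefix. It need not read the same sequence and may favour B73 as well, so this comparison cannot settle the question. Where a second probe set showed at least 50% of the difference in the same direction the odds ratio was 9.0 (0.417 to 587). It rested on 3 B73 probe sets, of which a pair share 1 cluster number, and left this explanation open. Of the 556 line-specific probe sets 71 had a second probe set, which showed this much of the difference for 44 and not for 27. Among the 44 were 2 higher and 1 lower in B73, and 7 and 34 in the other lines. Among the 27 were 4 higher and 2 lower in B73, and 6 and 15 in the other lines. B73 replicate 3 array 1 was excluded as the cause, since without it 74.6% of the B73-specific probe sets were higher, against 68.7% with it. The B73 counts were 123 higher and 85 lower with a pseudocount of 1, and 50 and 12 with 64.

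W23 replicates 2 and 3 were far more alike than other replicates of a line, with an SD of log2 differences of 0.197 against 0.390 to 0.811 in the other 11 pairs. For a single labelled RNA hybridised under 2 replicate numbers, the test compared arrays. It found 234 probe sets differing between the arrays of the replicates and 0 between first and second technical arrays. This cannot exclude 1 labelled RNA, since arrays handled apart under each number would differ too. The technical comparison also grouped 1 array of each replicate, so differences between the replicates widened its spread. The deviations of W23 replicate 2 correlated with those of replicate 3 of each other line with r of at least 0.38, and with those of replicate 2 between -0.64 and -0.37. If W23 replicate 2 came from the growth of replicate 3, its lowest correlation should be with replicate 1, since deviations within a line sum to 0, but there r lay between -0.25 and -0.18. W23 replicate 1 correlated with replicate 2 of the other lines (0.42 to 0.56) more than with replicate 1 (0.25 to 0.30). A shared growth therefore stays open, as does 1 RNA under 2 replicate numbers, labelled once or separately. Fewer than 3 independent W23 replicates would make p-values too small, in pairs without W23 as well, since all lines share 1 estimate of the spread.

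Other groupings of the replicates were tried for each count. Replicates were exchanged freely across replicate numbers, so the splits do not keep the pairing by number. Splits that mix lines also carry the line differences into the spread within groups. Low counts in them therefore do not show how many calls there would be if the lines did not differ. Of 100 splits of the 12 replicates into 4 groups, the real one included, 1 had as many probe sets differing among groups as the real 2549 (highest other 758). For probe sets higher in 1 line it was 1 split in B73 (92, highest other 76), 2 in Mo17 (49, 55), 2 in W23 (48, 76) and 4 in Wf9 (33, 52). For those lower it was 4 in B73 (42, 79), 1 in Mo17 (91, 76), 1 in W23 (99, 72) and 1 in Wf9 (102, 88). Each other split as large kept the 3 replicates of 1 line together. For list shifts all 100 splits had at least the real 0, which could not come out otherwise, and the highest other had 16. For pairs only 10 splits exist, too few for a test, and 1 of 10, the real one, was as large in each. The highest other was 0 for B73 against Mo17 (1223), 3 for B73 against W23 (1335), 1 for B73 against Wf9 (1207), 0 for Mo17 against W23 (1159), 0 for Mo17 against Wf9 (1361) and 0 for W23 against Wf9 (1273).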
